A study of Mus musculus with 12 samples.

How the data were processed

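The series holds RNA sequencing of 12 libraries from Mus musculus: hippocampus and cerebellum of 3 Syt14 knockout and 3 wild-type animals. The animal numbers in the labels show that the same 6 animals gave both tissues. Replicates are separate animals. Per the extract protocol, poly(A) RNA was selected and libraries were strand-specific by dUTP. The submitters' processing notes name Trimmomatic 0.39, STAR 2.7.10 and featureCounts 2.0.3 with the builds mm10 and GRCm38. The annotation release and the strand setting of the counting are not given in the sources used here. The deposited values are raw counts per gene, 1 table per tissue with the same 54446 gene identifiers. The values are whole numbers with a different total in each column, and no column had been scaled.

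Gene identifiers were looked up in GENCODE M21 for GRCm38 to get symbols, positions and biotypes, and 54409 of 54446 matched. Samples were grouped by tissue and genotype as labelled. Totals per library were 24355572 to 34971359 counts, of which 97.6 to 98.1% lay in protein coding genes. No pair of libraries of the same group was identical: the chi-square per gene between them was 3.91 to 11.6, where resampling of 1 library would give about 1. Floors cover counting error only. The 95% intervals of Syt14 rest on the SE of the fit over 3 animals per group and so include variation between animals. Normalized levels are CPM scaled by TMM factors, and marker levels of neighbouring tissues are plain CPM. Means carry the SD over 3 libraries and log2 fold changes the SE, computed as the size of the change over the square root of F.

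Differential expression used edgeR 4.0.16 in R 4.3.3, with filterByExpr (minimum count 10, minimum total 15), TMM factors, and the quasi-likelihood fit and two-sided test. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Each tissue was fitted alone with the genotype. The difference of the genotype effect between tissues was fitted over all 12 libraries, and the wild-type tissues over 6. The common biological coefficient of variation was 7.54% in the hippocampus and 8.23% in the cerebellum. Syt14 was also tested with a two-sided exact permutation test of log2 CPM. The effects in the tissues were compared by correlation across genes and by one-sided Fisher exact tests. Genes within 10 Mb of Syt14 were compared with all others, Syt14 left out. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.

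Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists with at least 5 tested members. There are 47 lists: 23 of biology, 21 of cell types and 3 technical. Syt14 was left out of every list. The sex-linked list had 4 tested members and was not tested. The strain-variable genes had an adjusted p of 0.606 in the hippocampus and 0.670 in the cerebellum, and the targets of nonsense-mediated decay 0.304 and 0.998. A preset correlation treats the members of a list as nearly independent, so each call was repeated with an estimated correlation. The lists were also tested with fry, whose directional test asks whether the genes of a list move, on balance, in 1 direction and whose mixed test asks whether they change in either direction. Neither compares a list with other genes. The directional test called 0 lists in the hippocampus and 1 in the cerebellum, the oligodendrocyte precursors (adjusted p = 0.0443), and the mixed test 0 and 5. Median, mean and test differed in sign in 11 of the 39 lists not called in the hippocampus, and in 9 of the 31 not called and 1 of the 15 called in the cerebellum.

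The tests, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. By that rule the text names Syt14, then up to 12 genes that rose and 12 that fell with the largest change among those past the threshold with at least 1 CPM and groups that do not overlap. Where fewer than 10 genes pass, it fills up to 10 with the smallest unadjusted p. From each called list it names up to 3 members by smallest p, for the difference between tissues up to 6 genes, and for the wild-type tissues the 2 members of each marker list with the largest fold. Predicted genes are counted and not named by the rule. Any other gene in the text was chosen after its values were seen. Values of some genes that the rule or a small count would name are not reported here.

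The fits were tested on simulated data, in which 50 genes were changed at each of several folds. Of the 50, the hippocampus fit (17410 genes) recovered 13 at 1.25-fold, 35 at 1.5-fold, 29 at 2-fold and 45 at 4-fold, with 9 false calls. The cerebellum fit (17525 genes) recovered 14, 24, 31 and 46, with 9 false calls, and the fit of the difference (18785 genes) 4, 15, 29 and 38, with 10. The wild-type tissue fit (17675 genes) recovered 20, 28, 44 and 47, with 19. A list of 20 genes shifted by 1.2-fold was called by camera in both tissues with the preset correlation (adjusted p = 4.09e-07 and 7.30e-14). With an estimated correlation its adjusted p was 0.503 and 0.0451. At the preset correlation no other list was called, but the counts were simulated independently for each gene. The simulation therefore cannot show the false calls that correlated members of a list would bring. Genes of all folds were changed together, so the adjusted threshold was easier to pass than where few genes change. The recoveries therefore overstate the power to find a few isolated changes.

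Pairing was checked by correlating, across genes, the deviations of the libraries from their group means. In the cerebellum, knockout and wild-type libraries of the same replicate number correlated at 0.150, 0.279 and 0.347, so the fit with that number as a block is given beside the result, although the animals differ. The hippocampus gave -0.0507, 0.119 and 0.274 and was not taken as paired. The tissues are paired by animal according to the labels, with correlations of 0.0301 to 0.155 between the tissues of 1 animal.

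The alternatives were DESeq2 1.42.0, limma-voom, median-of-ratios and upper-quartile factors, a filter of 1 CPM in 3 libraries, no filter beyond 1 count, adjusted p under 0.1, a 1.5-fold minimum, no sex-linked, mitochondrial or blood genes, all 12 libraries in 1 fit, the replicate number or animal as a block, and each library left out in turn. Other windows around Syt14 of 2, 5 and 20 Mb and a minimum of 5 CPM for the correlation were tried too. Alternatives added after the data were seen were covariates for choroid plexus, brainstem (a list of 21 genes written after the data were seen) and meninges, the cerebellum without knockout libraries 1 and 2, and the lists in the difference between tissues.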

Results

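Poly(A) RNA was sequenced from the hippocampus and the cerebellum of 3 mice labelled as Syt14 knockout and 3 wild-type mice, which gave 12 libraries in 4 groups of 3. Each animal gave both tissues, and no animal served in more than 1 genotype. The hippocampus libraries held 24932098 to 30504437 counts and the cerebellum libraries 24355572 to 34971359. Between 25048 and 26672 genes had at least 1 count in a library, and a floor of 3 counts corresponds to 0.0858 to 0.123 CPM, the counts of a gene scaled to the total of its library. Transcripts of the mitochondrial genome took 3.76 to 4.52% of the counts and the 10 most abundant genes 4.65 to 5.37%. Ddx3y, a gene on the Y chromosome, was read at 67.7 to 104 CPM in all 12 libraries, and Xist, the RNA of the inactive X chromosome, by 4 to 10 counts.

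Syt14, the gene altered in the knockout mice, encodes a member of the synaptotagmin family of membrane trafficking proteins. Scaled to library size, its level lay lower in every knockout library than in every wild-type library of the same tissue, at most of the wild-type level. In the hippocampus the knockout libraries held 27.8, 26.8 and 29.2 CPM and the wild-type libraries 36.6, 37.2 and 36.2 CPM, or 27.9 ± 1.22 against 36.7 ± 0.495 CPM (SD, n = 3). The knockout level was 76.1% of wild type, with a 95% interval of 69.97 to 82.8%, and by unadjusted p Syt14 ranked 1 among the genes tested in that tissue and 245 in the cerebellum. In the cerebellum the knockout libraries held 32.1, 32.3 and 31.7 CPM and the wild-type libraries 35.4, 35.2 and 39.9 CPM, which put the knockout at 86.9% of wild type with an interval of 79.8 to 94.7%. Neither difference passed the test over all genes. The log2 fold change was -0.39 ± 0.06 (SE, n = 3) in the hippocampus, with an unadjusted edgeR p of 3.88e-05 and an adjusted p of 0.686. In the cerebellum it was -0.20 ± 0.06, with an unadjusted edgeR p of 0.00897 and an adjusted p of 0.644. Syt14 was named before the data were examined, so its unadjusted p can be read beside the adjusted one. The two-sided exact permutation test of log2 CPM gave p = 0.1 in both tissues, the smallest p that 3 against 3 libraries allow. In the hippocampus the adjusted p of Syt14 ranged from 3.22e-04 to 0.9998 over the 16 alternative settings, and it passed with DESeq2 (adjusted p = 0.0196) and without a filter on low counts (3.22e-04). The edgeR fit without a filter also called Slc13a4 (adjusted p = 9.78e-07), whose change followed single libraries. Its p-values may therefore understate the variation between animals. Syt14 (ENSMUSG00000016200) lies on the minus strand of chromosome 1 from 192891233 to 193035775 in GRCm38, with 11932 bases of annotated exons. Which part of the gene was altered is not given in the sources used here, gene-level counts from outside an altered part check nothing about the knockout, and counts per exon are not analysed here.

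**Figure D1:**
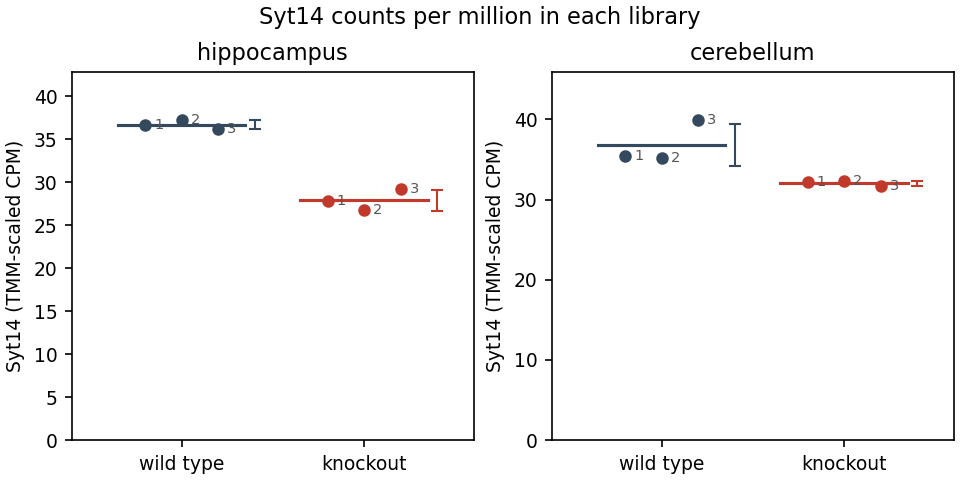
Syt14 in TMM-scaled CPM in each of the 12 libraries, with a point per animal labelled by its replicate number, the group mean as a line and the SD as a bar. The hippocampus knockout libraries lie between 26.8 and 29.2 CPM, below the wild-type libraries at 36.2 to 37.2 CPM, and the cerebellum knockout libraries between 31.7 and 32.3 CPM, below 35.2 to 39.9 CPM.

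The hippocampus comparison asked how gene expression differs with the Syt14 knockout genotype in a region tied to mood. No gene passed the test. The genes with the smallest unadjusted p after Syt14 were Ptprb, a receptor phosphatase of blood vessel endothelium, at 46.4 against 58.7 CPM (knockout against wild type, n = 3), and Slc7a11, the cystine and glutamate exchanger, at 46.3 against 59.9 CPM. Their log2 fold changes were -0.34 ± 0.06 and -0.37 ± 0.07 (SE). Per1, a gene of the circadian clock, stood at 100.75 ± 3.88 against 81.6 CPM, with a log2 fold change of 0.30 ± 0.06. Dnajb5, a heat shock co-chaperone, had 0.23, Dusp5, a phosphatase of the ERK kinases, 0.39, Tent5a 0.58 and Tiparp, an ADP-ribosyltransferase, 0.40 on the log2 scale. Eng, a co-receptor for TGF-beta in endothelium, had -0.37, Slc8a1, a sodium and calcium exchanger, -0.29, and AB124611, near the floor at 0.538 against 0.111 CPM, 2.23 ± 0.51. None of these genes passed.

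Of 17693 genes tested with edgeR, 0 passed at an adjusted p under 0.05, and 767 had an unadjusted p under 0.05 (454 higher and 313 lower in the knockout), where chance alone gives 884.65. limma-voom called 0 genes. DESeq2 called 4 genes, of which Per1 rose (adjusted p = 0.0356) and Syt14, Slc7a11 (0.0196) and Ptprb (0.0247) fell. Without knockout library 3 edgeR called 2 genes, both lower in the knockout, among them Tshz2 (log2 -1.11, adjusted p = 0.0347), which was named after its values were seen. In 1716 genes (9.70%) the ranges of the groups did not overlap, where chance gives 10%.

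Of the 46 gene lists tested in the hippocampus with camera at a preset correlation, 7 were called, 2 higher and 5 lower in the knockout. The genes of cholesterol synthesis lay higher, with a median log2 fold change of 0.11 over 24 members of which 23 were above 0 (adjusted p = 5.2e-05, and adjusted p = 0.848 with an estimated correlation). Examples are Cyp51, a sterol demethylase, at 0.18 and Mvd, an enzyme of the mevalonate steps, at 0.27. The immediate early genes, which neurons switch on after activity, had a median of 0.15 with 21 of 24 members above 0 (adjusted p = 0.00101, and adjusted p = 0.848 with an estimated correlation), among them Egr4 at 0.44, Nr4a1 at 0.41 and Dusp6 at 0.21. Markers of endothelium and pericytes lay lower, with a median of -0.19 and 18 of 19 members below 0 (adjusted p = 1.52e-05, and adjusted p = 0.848 with an estimated correlation). Adjusted over the list alone, 7 of these vessel genes fell, among them Itm2a (-0.25), Pltp (-0.22), Slco1a4 (-0.25) and Cldn5 (-0.43), a protein of the tight junctions of the blood-brain barrier. Markers of meninges and fibroblasts had a median of -0.64 over 17 members (adjusted p = 8.4e-05, and adjusted p = 0.848 with an estimated correlation), with Slc13a4 at -0.89, Slc6a13 at -0.58 and Slc6a20a at -0.64. Without wild-type library 2 these genes had -0.37, -0.37 and -0.18, and Slc13a4 had -1.34 without knockout library 3, as Nr4a1 had 0.26. The interferon response and MHC class I genes had a median of -0.20 over 30 members (adjusted p = 5.40e-04, and adjusted p = 0.848 with an estimated correlation), with Usp18 at -1.09, H2-D1 at -0.33 and B2m at -0.21. The cytosolic ribosomal proteins had a median of -0.04 with 65 of 78 members below 0 (adjusted p = 2.63e-04, and adjusted p = 0.848 with an estimated correlation). Oxidative phosphorylation had a median of -0.03 with 55 of 73 below 0 (adjusted p = 0.00318, and adjusted p = 0.848 with an estimated correlation). Rpl37 (-0.18) and Rps27 (-0.20) of the ribosome and Uqcr11 (-0.19) and Ndufb3 (-0.16) of the respiratory chain are examples. Over all genes 0 members of any of the 7 lists rose or fell.

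Meningeal transcripts differed between the libraries, and the interferon list moved with them. The mean log2 CPM of the meninges markers was 1.92, 2.01 and 2.76 in the knockout libraries and 2.68, 3.64 and 2.34 in the wild-type libraries. Without wild-type library 2, the richest in them, the meninges list had a median of -0.15 (adjusted p = 0.196) and the interferon and MHC class I list a median of -0.087 (0.247), while without wild-type library 1 the interferon median was -0.31. With the meninges score as a covariate, chosen after the data were seen, the interferon list had -0.039 (adjusted p = 0.489). The immediate early genes lost the call in both settings (adjusted p = 0.158 and 0.195), with medians of 0.11 and 0.13 beside the 0.15 of all libraries. The immediate early genes also lost the call without knockout library 3 (adjusted p = 0.0540), oxidative phosphorylation without knockout library 1 (median -0.022, 0.140) or wild-type library 3 (-0.012, 0.324), and the ribosomal proteins without knockout library 2 (-0.028, 0.0965) or wild-type library 3 (-0.0033, 0.662). Without wild-type library 2 these medians were -0.051 and -0.080, and without knockout library 3 that of the ribosomal proteins was -0.066 and that of oxidative phosphorylation -0.049. Without wild-type library 3 the immediate early gene median was 0.32. Cholesterol synthesis and the endothelium and pericyte markers kept the call with each library left out in turn, cholesterol synthesis with a median of 0.060 without knockout library 3.

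The lists closest to the question of the study were not called in the hippocampus. The other synaptotagmins had an adjusted p of 0.581, the SNARE and vesicle fusion genes 0.606, the ionotropic glutamate receptors 0.606, the mood disorder genes 0.853 and the cerebellar ataxia genes 0.745. Adjusted over the list alone, Per1 rose in the circadian clock list, and Per1 and Errfi1 (log2 0.22), an inhibitor of the EGF receptor, rose in the glucocorticoid response list. Neither list was called (adjusted p = 0.227 and 0.564).

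The cerebellum comparison asked the same of a region that governs motor coordination. Cck and Fosl2 rose in the knockout. Cck, the neuropeptide cholecystokinin, stood at 55.2 ± 2.89 CPM in the knockout against 29.9 ± 2.17 CPM in the wild type (SD, n = 3), a 1.85-fold difference. Fosl2, a transcription factor of the AP-1 family, stood at 19.7 ± 1.41 against 8.90 ± 0.593 CPM, a 2.21-fold difference. For each gene all 3 knockout libraries lay above all 3 wild-type libraries. The edgeR log2 fold changes were 0.89 ± 0.07 for Cck and 1.146 ± 0.09 for Fosl2 (SE), each with an adjusted p of 0.00157. Both were called under all 18 alternative settings, with log2 fold changes of 0.82 to 0.93 for Cck and 1.08 to 1.26 for Fosl2.

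**Figure D2:**
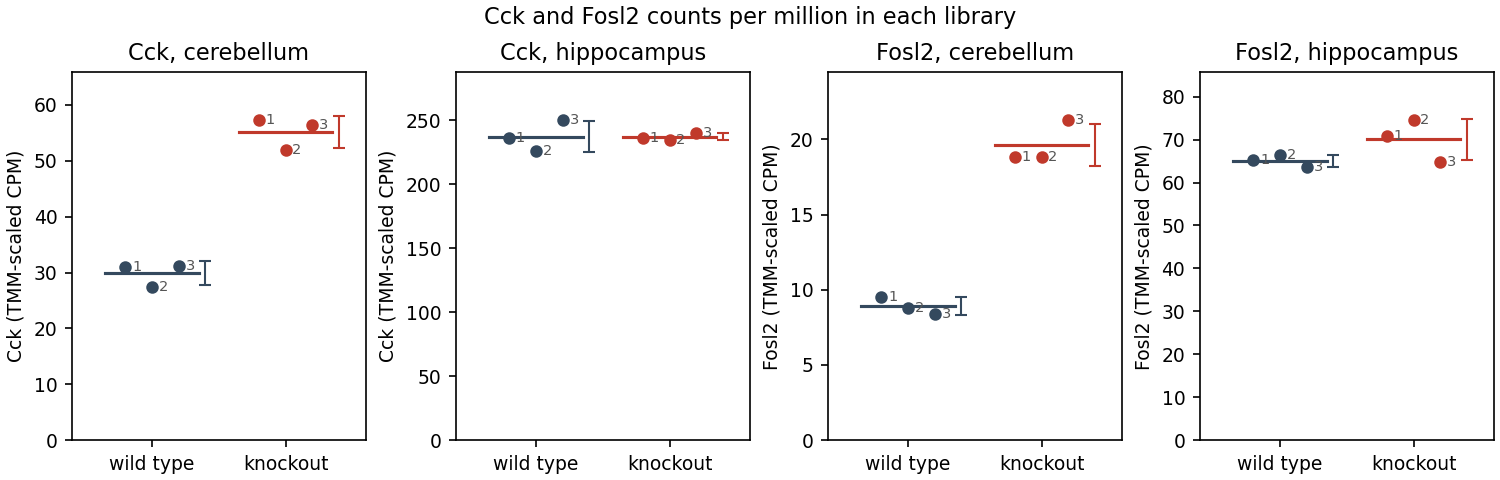
Cck and Fosl2 in TMM-scaled CPM in each library of the cerebellum and the hippocampus, with a point per animal labelled by its replicate number, the group mean as a line and the SD as a bar. In the cerebellum Cck averaged 55.2 CPM in the knockout against 29.9 in the wild type and Fosl2 19.7 against 8.90, while in the hippocampus Cck averaged 237.08 against 237.14 and Fosl2 70.1 against 65.1.

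Next in order of p, and not past the test, came C4b, a component of complement, at 20.7 against 14.05 CPM (log2 0.56), Nr4a2, an orphan nuclear receptor induced by activity, at 49.7 against 29.5 CPM (0.76), and Gng4, a G protein gamma subunit, at 14.2 against 7.26 CPM (0.97). All 3 had an edgeR adjusted p of 0.0559. Prl2c3, of the prolactin family, had a log2 fold change of 1.29 (adjusted p = 0.0753), and Ryr3, a calcium release channel, 0.60 (0.269). Tnc, the matrix protein tenascin C, stood at 11.8 against 19.3 CPM (log2 -0.70, adjusted p = 0.217), and Mybpc1, a myosin-binding protein, at 37.0 against 50.8 CPM (-0.45, 0.269). C1qb, a complement gene of microglia, stood at 14.2 against 10.3 CPM (0.47, 0.269).

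Of 17733 genes tested in the cerebellum, 2 passed, and 1200 had an unadjusted p under 0.05 (683 higher and 517 lower), where chance alone gives 886.65. Another split of the same libraries, with the genotypes mixed, gave 1692 such genes, so an excess can arise without the genotype. limma-voom called 2 genes and DESeq2 38 (26 that rose and 12 that fell). Samples of the same replicate number, although from different animals, resembled each other in this tissue, and with that number as a block 36 genes were called, of which 20 rose and 16 fell. The blocked fit kept Cck (adjusted p = 1.74e-04) and Fosl2 (0.00241), and in it Nr4a1 (0.60), Nr4a2 (0.76), Dusp1 (0.50), Bdnf (0.46), Scg2 (0.40), C4b (0.56) and Gfap (0.32) rose and Calb2 (-0.32) and Tnc (-0.70) fell. The choroid plexus genes Otx2 (-0.51), Clic6 (-1.02), Ace (-0.94), Abca4 (-1.48) and Slc4a2 (-0.37) fell in it too, and choroid plexus was nearly absent from knockout library 3 (Ttr at 0.622 CPM). Of the fixed lists, the immediate early genes had 4 members that rose in it, the neurotrophins and neuropeptides 3 and the glial reaction genes 2. The choroid plexus markers had 2 members that fell. Without knockout library 3, 33 genes were called (29 rose, 4 fell). They include the brainstem genes Dbh (3.48), Slc6a2 (3.54), Slc5a7 (3.01), Slc10a4 (3.26), Gata3 (3.18) and Shox2 (6.08), as the 2 knockout libraries left are those richest in brainstem transcripts. Without wild-type library 3, 4 genes were called: Cck, Fosl2, Fos (1.24) and Nr4a3 (1.01). A fit of all 12 libraries called 4 as well, with 1700016P03Rik (1.79) and C4b (0.56) beside Cck and Fosl2. Genes named from these alternative fits were chosen after their values were seen. The ranges of the groups did not overlap in 2104 genes (11.9%), where chance gives 10%.

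In the cerebellum 15 of 46 lists were called, 10 higher and 5 lower in the knockout, and each lost the call with an estimated correlation. The microglia markers lay higher, with a median log2 fold change of 0.18 and 14 of 16 members above 0 (adjusted p = 3.95e-06). The glial reaction genes, which astrocytes and microglia raise after injury, had a median of 0.25 over 22 members (adjusted p = 3.95e-06). Both lists had an adjusted p = 0.440 with an estimated correlation, and they share 3 genes. The mean log2 CPM of the microglia markers was 3.1998, 3.22 and 3.09 in the knockout and 2.86, 2.92 and 3.02 in the wild type, and that of the glial reaction genes 2.67, 2.91 and 2.50 against 2.29, 2.37 and 2.25, so both were highest in the knockout libraries richest in brainstem transcripts. Knockout library 3, with the brainstem genes Slc6a2 and Dbh below every wild-type library, still lay above every wild-type library in both. At the preset correlation both lists kept the call with each library left out in turn. Adjusted over the list alone, 5 microglia markers rose, among them the complement genes C1qa (0.51), C1qb (0.47) and C1qc (0.39). In the glial reaction list 7 genes rose adjusted over the list alone, among them C4b (0.56), the astrocyte filament gene Gfap (0.32, at 213 against 171 CPM) and the lysosomal gene Cd68 (0.71). The immediate early genes had a median of 0.19 over 23 members (adjusted p = 8.73e-05, and adjusted p = 0.483 with an estimated correlation). In that list 1 gene, Fosl2, rose over all genes, and adjusted over the list alone 5 rose (Fosl2, Nr4a1, Nr4a2, Nr4a3 and Fos) and Ier5 fell. The neurotrophins and neuropeptides had a median of 0.32 over 25 members (adjusted p = 0.00118, and adjusted p = 0.584 with an estimated correlation). There Cck rose over all genes, and adjusted over the list alone Cck, Bdnf (0.46), the brain-derived neurotrophic factor, and Scg2 (0.41), a granin of secretory vesicles, rose. The mean log2 CPM of the neuropeptide list was 3.17, 2.90 and 2.49 in the knockout and 2.65, 2.52 and 2.40 in the wild type, so it was highest in the libraries richest in brainstem transcripts. Without knockout library 1 it had a median of 0.051 and an adjusted p of 0.0992, and with the brainstem score as a covariate, a setting chosen after the data were seen, 0.11 and 0.0716. The neuropeptide median was 0.18 without knockout library 2 and 0.16 without wild-type library 1, and that of the glial reaction genes 0.44 without knockout library 3 and 0.39 without wild-type library 1. With the brainstem covariate the medians of the microglia, glial reaction and immediate early gene lists were 0.12, 0.18 and 0.26, and these 3 lists kept the call at the preset correlation (adjusted p = 0.512, 0.512 and 0.547 with an estimated correlation).

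Markers of oligodendrocytes and myelin had a median of 0.12 over 19 members (adjusted p = 1.26e-04, and adjusted p = 0.584 with an estimated correlation), with the myelin genes Mal at 0.18 and Ermn at 0.18. Those of oligodendrocyte precursors had a median of 0.19 over 11 members (adjusted p = 0.00397, and adjusted p = 0.440 with an estimated correlation), and Gpr17 (0.33) rose adjusted over the list alone. Both oligodendrocyte groups were highest in knockout libraries 1 and 2, with means of 6.80 and 6.85 against 6.67 to 6.78 and of 4.01 and 3.96 against 3.76 to 3.92 log2 CPM in the other libraries. The interferon and MHC class I genes had a median of 0.09 over 30 members (adjusted p = 0.00397, and adjusted p = 0.440 with an estimated correlation), with Iigp1 at 0.51 and Lgals3bp at -0.26. The ribosomal proteins had a median of 0.04 over 78 members (adjusted p = 0.00753, and adjusted p = 0.969 with an estimated correlation), with Rps29 at 0.20 (0.10 without knockout library 1) and Rps15a at -0.10. Endothelium and pericyte markers had a median of 0.10 over 19 members (adjusted p = 0.0109, and adjusted p = 0.544 with an estimated correlation), with Pecam1 at 0.19. Cholesterol synthesis had a median of 0.06 over 24 members (adjusted p = 0.0119, and adjusted p = 0.483 with an estimated correlation), with Cyp51 at 0.18 (0.11 without knockout library 1) and Idi1 at 0.17. With the brainstem covariate, a setting chosen after the data were seen, 3 of these 6 lists lost the call: the ribosomal proteins with a median of -0.00057 (adjusted p = 0.974), the interferon genes with 0.056 (0.0830) and cholesterol synthesis with 0.055 (0.153). The interferon median was 0.056 without knockout library 1, 0.18 without knockout library 3, 0.14 without wild-type library 1 and 0.15 without wild-type library 3. Leaving out 1 library ended several of these calls. The ribosomal list lost it without knockout library 1 (median 0.017, adjusted p = 0.411), knockout library 2 (0.024, 0.267) or wild-type library 3 (0.016, 0.645), and had a median of 0.089 without knockout library 3 and 0.070 without wild-type library 2. The endothelium list lost it without knockout library 1 (median 0.089, adjusted p = 0.0882), knockout library 3 (0.057, 0.17) or wild-type library 3 (0.036, 0.543). Cholesterol synthesis lost it without knockout library 1 (0.0992), knockout library 2 (0.0573) or wild-type library 2 (0.0664).

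Among the lists that lay lower, the choroid plexus markers had a median of -1.11 with all 18 members below 0 (adjusted p = 3.95e-06, and adjusted p = 0.812 with an estimated correlation). Enpp2, which makes lysophosphatidic acid, had -1.10, the bicarbonate transporter gene Slc4a5 -1.44 and Clic6 -0.89. These values follow single libraries: without knockout library 2 the median was -2.08 and Enpp2 -1.87, Slc4a5 -2.44 and Clic6 -1.52, and without knockout library 3 the median was -0.56 and these genes -0.65, -0.89 and -0.50. With the brainstem score as a covariate, a setting chosen after the data were seen, the choroid plexus median was -3.44 and that of ependyma -1.09. Ependyma markers had a median of -0.36 over 13 members (adjusted p = 0.00231, and adjusted p = 0.920 with an estimated correlation), and Hydin (-0.41), a gene of motile cilia, fell adjusted over the list alone. Granule cell markers had a median of -0.09 over 17 members (adjusted p = 0.00328, and adjusted p = 0.969 with an estimated correlation), with Calb2, the calcium-binding protein calretinin, down adjusted over the list alone (-0.32). Chn2 (-0.18) and Etv1 (-0.15) did not pass. Bergmann glia markers had a median of -0.10 over 12 members (adjusted p = 0.0146, and adjusted p = 0.671 with an estimated correlation), and Fabp7 (-0.45), a fatty acid-binding protein of these cells, fell adjusted over the list alone, with -0.27 without wild-type library 3. The thalamus and habenula list was called lower (adjusted p = 0.0435, and adjusted p = 0.483 with an estimated correlation) with a median of -0.07 over 13 members but a mean of 0.26. In it Calb2 and Patj (-0.19) fell adjusted over the list alone, while Nrgn, a postsynaptic gene of forebrain neurons, stood at 49.3, 3.84 and 3.54 CPM in the knockout against 3.94, 2.79 and 2.54 CPM in the wild type. With the replicate number as a block the Bergmann glia (median -0.098, adjusted p = 0.0509) and thalamus lists (-0.064, 0.0923) lost the call, though their medians hardly moved. Oxidative phosphorylation gained the call in that fit (0.030, 0.0308). With the same covariate the granule cell median was -0.016 (adjusted p = 0.704), and the Bergmann glia (-0.092, adjusted p = 0.120) and thalamus lists (-0.032, 0.259) lost the call as well. The ependyma list lost the call without knockout library 3, with a median of -0.00064 (adjusted p = 0.261), or wild-type library 2, with -0.083 (0.0529), and had -0.95 without knockout library 2 and -0.59 without wild-type library 3. The granule cell list lost it without knockout library 2, with -0.029 (0.428), or wild-type library 1, with -0.055 (0.0579), and had -0.15 without knockout library 3 (4.27e-06). The Bergmann glia list lost it without knockout library 1, with a median of -0.057 (0.171), or wild-type library 1 (0.138), and the thalamus list without knockout library 2, with -0.046 (0.354), knockout library 3 (0.0777), wild-type library 1 (0.118) or wild-type library 3 (0.0703).

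Transcripts of tissue next to the cerebellum differed between its libraries. Ttr, the transthyretin gene of choroid plexus, was read at 922, 1688 and 0.622 CPM in the knockout libraries and at 1792, 2547 and 959 CPM in the wild-type libraries, with 18 counts in knockout library 3. Slc6a2, the noradrenaline transporter of brainstem neurons, was read at 6.71, 15.5 and 0.242 CPM in the knockout and 2.05, 0.458 and 0.535 CPM in the wild type. Dbh, which makes noradrenaline, was read at 3.61, 10.8 and 0.104 against 1.11, 0.372 and 0.535 CPM. The ependyma list moved with the choroid plexus markers: with the mean of these as a covariate the ependyma list had a median of 0.33 (adjusted p = 0.729). Brainstem transcripts were richest in knockout libraries 1 and 2. The monoamine list moved with them, with a mean log2 CPM of 2.04, 2.10 and 1.002 in the knockout and 1.39, 1.28 and 1.30 in the wild type. Knockout library 1 also held more transcripts of striatal neurons, with a marker mean of 2.49 against 1.26 to 1.58 in the other 5 libraries. With the choroid plexus covariate 32 genes were called, with a brainstem covariate 90, and without knockout libraries 1 and 2 together 64, all settings chosen after the data were seen. The 32 include the brainstem genes Dbh (4.02), Slc6a2 (4.09), Slc10a4 (3.79), Slc5a7 (3.32) and Slc18a2 (1.251). Cck and Fosl2 were called under each of these settings.

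**Figure D3:**
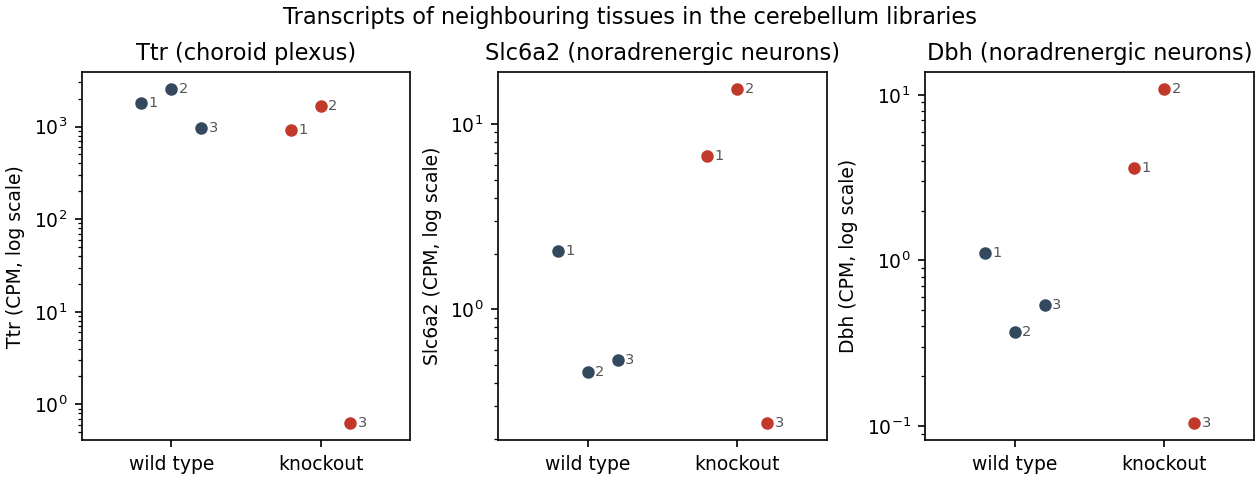
Ttr, Slc6a2 and Dbh in CPM on a log scale in the 6 cerebellum libraries, with a point per animal labelled by its replicate number. Ttr is at 0.622 CPM in knockout library 3 and between 922 and 2547 CPM in the other 5 libraries, and Slc6a2 is at 6.71 and 15.5 CPM in knockout libraries 1 and 2 and at most 2.05 CPM in the others.

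The lists for synapses, mood and ataxia were not called in the cerebellum. The other synaptotagmins had an adjusted p of 0.573, the SNARE and vesicle fusion genes 0.824, the ataxia genes 0.441 and the mood disorder genes 0.596, with Bdnf the member of the last that rose adjusted over the list alone. Adjusted over the list alone, Kcna4 (0.82) rose and Kcnh1 (-0.29) fell among the potassium channels, and Ryr3 rose and the calcium pump gene Atp2b3 (-0.24) fell among the calcium signalling genes. The monoamine signalling list, which holds Slc6a2 and Dbh, had an adjusted p of 0.0726.

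Whether the effect of the genotype differed between the tissues was tested over all 12 libraries. Cck and Fosl2 differed: in the hippocampus Cck stood at 237.08 against 237.14 CPM (n = 3), with a log2 fold change of -0.00034, and Fosl2 at 70.1 against 65.1 CPM, with 0.11. The difference of the effects, hippocampus less cerebellum, was -0.89 ± 0.08 (SE) for Cck and -1.05 ± 0.10 for Fosl2, each with an edgeR adjusted p of 3.71e-04. With the animal as a block both were called as well (adjusted p = 0.00116 and 0.0155). Of 19027 genes 2 passed, and 1016 had an unadjusted p under 0.05, where chance gives 951.35. DESeq2 called 11. The next genes did not pass: C4b at -0.65 (adjusted p = 0.210), C1qc at -0.55, the lipase gene Lpl at -1.66 and Crhbp, which binds corticotropin-releasing hormone, at -2.49 (each 0.701). Crhbp lay near the floor in the cerebellum, with 23, 20 and 8 counts in the knockout libraries, the most in those richest in brainstem transcripts, and 4, 3 and 3 in the wild type. Without knockout animal 3, 56 genes were called (2 higher, 54 lower), and without wild-type animal 1, 4 were called: Cck, Fosl2, C4b (-0.75) and Hydin (1.45), the last named after its value was seen. Of the lists, 12 were called in this contrast, and each lost the call, with an adjusted p between 0.154 and 0.860 with an estimated correlation. Endothelium and pericytes (median -0.27), interferon and MHC class I (-0.30), the ribosomal proteins (-0.08) and the meninges (-0.63) had a lower knockout effect in the hippocampus than in the cerebellum. The choroid plexus (0.95) and ependyma (0.48) had a higher one. These are differences of log2 fold changes and not of marker levels.

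Across the 16592 genes tested in both tissues, the log2 fold changes of the hippocampus and the cerebellum had a Pearson r of 0.0540 and a Spearman rho of 0.0666. At an unadjusted p under 0.05, 41 genes were higher in the knockout in both tissues where chance gives 16.5 (one-sided Fisher exact p = 7.45e-08), and 15 were lower in both where chance gives 8.78 (p = 0.0312). The Fisher test treats genes as independent, which they are not, and the same 6 animals gave both tissues: another split of these animals gave 62 genes higher and 92 lower in both. No gene passed the edgeR test in both tissues. The correlation was -0.00794 without wild-type animal 1, 0.00665 without knockout animal 3 and 0.101 without wild-type animal 2.

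Genes beside Syt14 on chromosome 1 were compared with the rest of the genome, since a targeted allele can carry flanking sequence of another strain. Within 10 Mb of Syt14, edgeR called 0 of 98 genes in the hippocampus and 0 of 89 in the cerebellum. Elsewhere it called 0 and 2 genes, so these counts could hardly have differed. At an unadjusted p under 0.05 there were 5 (5.10% against 4.33% elsewhere, one-sided Fisher exact p = 0.420) and 7 (7.87% against 6.76%, p = 0.397). Sertad4, at 17.4 against 22.2 CPM in the hippocampus (log2 -0.35), and Kcnh1, a potassium channel gene at 66.7 against 81.4 CPM in the cerebellum (-0.29), were among them. Nek2, a kinase of the cell cycle, had 0.45 and Hsd11b1, which regenerates glucocorticoids, -0.20 in the cerebellum. In the other tissue Sertad4 had 0.09, Kcnh1 -0.02, Hsd11b1 -0.06 and Nek2, at under 1 CPM, 0.42. These genes were named after their values were seen. With edgeR none passed, while DESeq2 called Kcnh1 in the cerebellum (log2 -0.29, adjusted p = 0.00707). Within 2 Mb the median absolute log2 fold change was 0.159 in the hippocampus against 0.0732 elsewhere, and 0.116 in the cerebellum against 0.0763. Another split of the libraries, with the genotypes mixed, gave 0.174 and 0.118 within 2 Mb.

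The wild-type tissues were compared to check the tissue labels and the level of Syt14. Markers of hippocampal neurons were high in the hippocampus: Fibcd1, of CA1 pyramidal cells, stood at 174 against 0.767 CPM in the cerebellum (n = 3) and Mpped1 at 234 against 4.59. Rgs14, of CA2, stood at 95.1 against 0.191 CPM, Npy2r at 60.2 against 0.341 and Lct and Scgn, of dentate granule cells, at 51.1 against 0.330 and at 1.19 against 0 counts, which allows up to 0.0329 CPM over the 3 libraries. Markers of cerebellar cells were high in the cerebellum: the granule cell genes Gabra6 and Cbln3 stood at 603 and 1518 CPM against 0.0258 (2 counts) and 0.493. The Purkinje cell genes Ppp1r17 and Pcp2 stood at 195.4 and 169.2 CPM against 0.180 and 0.405, Dao and A2m of Bergmann glia at 57.7 and 95.1 against 0.196 and 3.85, and Tfap2b and Slc6a5 of Golgi cells at 66.4 and 53.2 against 5 and 3 counts. The hippocampus markers were higher there in 14 of 15 dentate granule cell genes, 11 of 11 CA1 genes and 11 of 15 CA2 and CA3 genes. The cerebellum markers were higher there in 16 of 17 granule cell genes, 18 of 20 Purkinje cell genes, 10 of 12 Bergmann glia genes and 9 of 11 unipolar brush and Golgi cell genes. Syt14 itself stood at 38.5 ± 0.422 CPM in the hippocampus and 35.0 ± 2.66 CPM in the cerebellum (SD, n = 3), a log2 difference of 0.14 that did not pass (edgeR adjusted p = 0.0790). Of 18128 genes, 11986 were called, 6005 higher and 5981 lower in the hippocampus, and 11948 with the animal as a block. The column names carry 1 token for all hippocampus libraries and another for all cerebellum libraries, so tissue and that token cannot be told apart, while both genotypes occur under each.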

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

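The tests of the Syt14 level, of Cck and Fosl2 and of the share of neurons, and the test of the gene lists for a difference between tissues, were chosen only after the result was seen. The brainstem test of the microglia list was written before its result. Each result of the next paragraph was singled out because the effect of the genotype differed between hippocampus and cerebellum in a test of the difference itself, and its values are the effect in the hippocampus less that in the cerebellum on the log2 scale unless given otherwise. The paragraphs after it weigh the Syt14 level, Cck and Fosl2, and the glial lists, with values from within a tissue.

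Cck differed by -0.89 and Fosl2 by -1.05, both called by edgeR over all genes. The list medians were -0.27 for endothelium and pericytes, -0.078 for the cytosolic ribosomal proteins, -0.31 for the glial reaction, -0.30 for interferon and MHC class I, -0.20 for microglia and -0.070 for oxidative phosphorylation. They were -0.36 for neurotrophins and neuropeptides, 0.95 for choroid plexus, -0.63 for meninges and fibroblasts, 0.48 for ependyma, -0.15 for oligodendrocyte precursors and -0.13 for oligodendrocytes and myelin. The choroid plexus and ependyma values depend on cerebellum knockout library 3, which held Ttr at 0.622 CPM against 922 to 2547 CPM in the other cerebellum libraries. The meninges value depends on hippocampus wild-type library 2, without which its median in that tissue was -0.15. Without the same library the interferon median there was -0.087, against -0.20 with all libraries. In the cerebellum the neuropeptide median was 0.051 without knockout library 1, against 0.32 with all libraries. All 12 lists were called at the preset correlation and none with an estimated correlation (adjusted p of 0.154 to 0.860).

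Syt14 in CPM was lower in every knockout library than in every wild-type library of its tissue, yet stayed at 76.1% of wild type in the hippocampus. The 1 annotated gene that overlaps Syt14 had 0 counts in the 12 libraries. This cannot decide whether reads of an overlapping gene add to Syt14. The annotation of the counting is not given, and reads that fit both genes may have been left out. Reads from exons outside the altered part may account for the remaining counts, and cannot be told apart from a transcript lowered along its whole length, because counts per exon were not analysed here. An exchange of a knockout and a wild-type library is argued against in the hippocampus only if the allele lowers the gene-level count. There the groups lay 7.03 CPM apart with SDs of 1.22 and 0.495 CPM. The exact permutation test gave p = 0.1, the smallest possible, so the separation alone cannot establish the labels. In the cerebellum an exchange cannot be told apart from a small effect of the allele: the gap was 2.94 CPM and the wild-type SD 2.64 CPM. The bound of 2 times the larger SD replaced, after these values were seen, a bound of 1 knockout SD (0.313 CPM) that both tissues passed.

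Cck and Fosl2 rose in the knockout cerebellum. Brainstem tissue as the whole cause is argued against: with the brainstem score as a covariate both stayed called, with the smaller log2 fold change at 0.92. The number of called genes went from 2 to 90, but most of these fell. The choroid plexus median went to -3.44 in that fit, so the 90 do not show that brainstem signal was removed. Choroid plexus as the whole cause is argued against by its own covariate, with the smaller log2 fold change at 0.84. The 32 genes called with it include brainstem genes. Handling shared by the knockout animals cannot be told apart from the genotype, as the immediate early genes had a median of 0.15 in their hippocampus too and no animal separates the 2. An effect of the genotype itself may be the source and stays open as a hypothesis.

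Microglia and glial reaction markers lay higher in the knockout cerebellum. A lower share of neurons would raise every glial marker alike, and the astrocyte and Bergmann glia scores argue against it as the only cause for the microglia markers. The astrocyte scores were 7.72, 7.78 and 7.76 in the knockout and 7.79, 7.74 and 7.79 in the wild type. Those of Bergmann glia were 5.87, 5.997 and 5.97 against 6.10, 5.98 and 5.95. A part played by the share of neurons is not settled. The microglia score less the mean of the astrocyte and Bergmann glia scores was higher by 0.28 in the knockout (SD 0.0918 and 0.117). In it 3 of 3 knockout libraries lay above all wild-type libraries, so these lists did not rise alike. The score leaves out the lists of oligodendrocytes and their precursors, which were called higher too. Granule cell markers were called lower, though not with the brainstem covariate (median -0.016, camera adjusted p = 0.704). With the replicate number as a block the pan-neuronal (median 0.020, camera adjusted p = 0.732) and Purkinje cell lists (-0.0083, 0.798) were not called. Brainstem tissue could also account for part of the rise in microglia markers. Knockout library 3, low in the brainstem transcripts Slc6a2 (0.242 CPM) and Dbh (0.104 CPM), had a microglia score of 3.09 against 2.86 to 3.02 in the wild type. With the brainstem covariate the microglia median was 0.12 with an adjusted p of 0.00169 (adjusted p = 0.512 with an estimated correlation). The rule written beforehand asked for a called list with a median over 0.1, which was met at the preset correlation. The median lay within its SE over members of 0.0610 of that bound, a margin that the rule did not ask for. That SE is over genes and not over animals, and the call was lost with an estimated correlation. A response of microglia to the genotype stays open and untested.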

How the results depend on the processing

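The covariates and the fit without knockout libraries 1 and 2 were chosen after seeing the data. Of the values that answer a comparison, 114 kept their direction and side of the threshold, or stayed within 1.5 times the count, 27 moved, 2 became stronger and 1 reversed. Of the values of single genes and lists, 1496 kept both, 108 gained a call, 83 lost it and 5 reversed. The cause was not tested.

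In the hippocampus the count of 0 genes became 4 with DESeq2 (1 up, 3 down) and 77 without a filter on low counts (36 up, 41 down), and Syt14 passed in both (log2 -0.40, adjusted p = 0.0196, and -0.40, 3.22e-04). With the replicate number as a block, in a tissue where that number did not pair the libraries, 2 genes were called, Arc (0.41) and Nr4a1 (0.40), while the 3 other splits that part all pairs gave 13, 0 and 5. Leaving out 1 library gave 0 to 2. The edgeR fit without a filter also called Slc13a4 (adjusted p = 9.78e-07), whose change followed single libraries. In both tissues the p-values without a filter may therefore understate the variation between animals. In the cerebellum the count of 2 became 38 with DESeq2 (26 up, 12 down), 417 without a filter (234 up), 7 at an adjusted p under 0.1, 4 with all 12 libraries in 1 fit and 36 with the replicate block. It became 32 with the choroid plexus covariate (26 up, 6 down), 90 with the brainstem covariate (13 up, 77 down) and 64 without knockout libraries 1 and 2 (7 up, 57 down), a fit in which the lone knockout library is assumed to vary like the wild type. Leaving out 1 library gave 2 to 33. Of the 36 genes of the blocked fit, 23 were also called by DESeq2, 13 with the choroid plexus covariate and 11 without knockout library 3.

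With an estimated correlation 0 lists were called in the hippocampus and 0 in the cerebellum, and fry called 0 and 1. Leaving out 1 library gave 5 to 8 lists in the hippocampus and 11 to 18 in the cerebellum, and the brainstem covariate 8 there (6 up, 2 down) against 15. Around Syt14, 5 genes in the hippocampus and 7 in the cerebellum had an unadjusted p under 0.05. The difference between tissues had 11 genes with DESeq2 and 2 to 56 with 1 animal left out. The correlation between tissues was 0.124 over genes with at least 5 CPM and -0.00794 to 0.101 with 1 animal left out, reversed without wild-type animal 1. Values that changed sign were the median of the meninges list with its own markers as covariate, which fixes that outcome (0.031), Rsph1 (0.024) and the ependyma list (0.33) with the choroid plexus covariate, the ribosomal list in the cerebellum with the brainstem covariate (-0.00057), and Cyp51 in the cerebellum without knockout libraries 1 and 2 (-0.0073). The wild-type tissues gave 11360 to 11601 genes with 1 library left out. Depth limits genes near the floor of 0.0858 to 0.123 CPM, and 3 animals per group limit small changes. Of 50 genes simulated at the smallest fold, 13 were recovered in the hippocampus and 14 in the cerebellum, and at 1.5-fold 35 and 24. Many genes were changed together there, which eases the adjusted threshold, so these recoveries overstate the power to find a few isolated changes.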

Other observations

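The tests of other splits of the samples were written before their results, and the genes of the next paragraphs were chosen after their values were seen.

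Immediate early genes did not move as 1 block. In the cerebellum Nr4a3, a nuclear receptor induced by activity, stood at 57.0, 47.4 and 50.5 CPM in the knockout and 28.4, 23.2 and 5.72 CPM in the wild type. Fos stood at 44.4, 42.1 and 50.7 against 21.2, 17.8 and 41.2 CPM, and Npas4, which neurons induce on calcium entry, at 6.73, 4.92 and 4.97 against 2.03, 2.62 and 5.02 CPM. Arc, a gene of synaptic plasticity, had a log2 fold change of -0.04 there, Egr1 -0.27 and Junb -0.10. In the hippocampus Arc had 0.42, Fosb 0.46 and Egr1 0.28. Of these genes Fos and Nr4a3 were past the test adjusted over the list alone, in the cerebellum, and none over all genes.

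Beside Cck and Fosl2, 9 genes were called in all 4 of the cerebellum fits with DESeq2, with the replicate block, with the choroid plexus covariate and without knockout library 3. They are C4b, Nr4a2, Gng4, Scg2, Lpl, Calb2, Tnc, 1700016P03Rik and 1700025G04Rik. These 4 fits were picked after the calls were seen, and the last 2 also call the brainstem genes Dbh, Slc6a2 and Slc5a7. Over all 18 alternatives Nr4a2 was called in 8, C4b in 7, Gng4 in 6 and Scg2, Calb2 and Tnc in 5, with Scg2 between 0.19 and 0.54 and Calb2 between -0.41 and -0.20. With the brainstem covariate Nr4a2, C4b and Gng4 were called, and Scg2 (0.30), Calb2 (-0.24) and Tnc (-0.64) were not. Lpl, the lipoprotein lipase, stood at 3.09, 2.33 and 1.63 CPM in the knockout and 0.747, 0.996 and 0.635 CPM in the wild type, and Calb2 at 286, 268.4 and 315 against 352, 354 and 378 CPM. Eomes, a gene of unipolar brush cells, rose in the blocked fit (log2 0.57, adjusted p = 0.0251), at 31.4, 33.35 and 19.6 against 23.4, 23.01 and 11.5 CPM. The list of unipolar brush and Golgi cells went the other way, with a median of -0.11 and 8 of 11 members below 0, and was not called (adjusted p = 0.0746).

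Each comparison was repeated on all 10 splits of its 6 samples into 3 and 3, the real one included, and 10 splits cannot give a share under 0.05. In the hippocampus the real count was 0, so all 10 splits gave at least as many by construction. The highest other gave 82 and the remaining ones 0 or 1. The split with 82 sets knockout libraries 1 and 2 with wild-type library 2 against the rest. Its count may reflect a structure of the samples that the genotype does not follow, which was not tested. In the cerebellum 3 of 10 splits gave at least the real 2 genes, and the highest other gave 2. The labels pair no animals across the genotypes. Pairs by replicate number were read from correlations among these same cerebellum libraries. The 3 other splits that part all 3 such pairs gave 0, 0 and 0 genes in the cerebellum. With the number as a block they gave 0, 0 and 0 against the real 36. So few splits, picked from the data, cannot give a share under 0.05 either. In the hippocampus, where that number does not pair the libraries, the same 3 splits gave 13, 0 and 5 with it as a block against the real 2. The other splits that gave 2 genes leave 2 pairs unparted. For the difference between tissues 1 split of 10 gave 2 genes, the real one, and the highest other gave 1. For the wild-type tissues 1 split gave 11986 genes, the real one, and the highest other 0.

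For the gene lists, 6 of 10 splits of the hippocampus libraries gave at least the real 7 lists, and the highest other gave 14. In the cerebellum 3 of 10 gave at least the real 15, and the highest other gave 19, while the 3 other splits that part all 3 pairs gave 8, 8 and 5. For the correlation of the effects between tissues, 6 of 10 splits of the animals gave at least the real 0.0540, and the highest other gave 0.126. Other splits gave up to 62 genes higher in both tissues and up to 92 lower in both, against the real 41 and 15. The median absolute log2 fold change within 2 Mb of Syt14 reached 0.174 in other splits of the hippocampus libraries and 0.118 in those of the cerebellum, against the real 0.159 and 0.116.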
